A study of Homo sapiens with 6 samples.

How the data were processed

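Gene expression was measured in cells labelled as the human ovarian cancer line SKOV3. Single-colour Illumina bead arrays were used, on which each array holds the cRNA of 1 sample. The 6 samples fall into 2 groups of 3 arrays: the parental subline SKOV3-ip1 and the metastatic subline SKOV3-OM3, called ip1 and OM3 here. Per the labels' protocols, total RNA was isolated with a mirVana kit, amplified to cRNA and labelled with biotin. The labels do not say that the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

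Of the tables used, the first holds linear probe intensity values as deposited by the authors, 48799 probes per array, which the submitters' processing notes trace to BeadStudio, with no version given. This intensity table has no detection p-values and no control probes. Its columns name the group but not the sample, so arrays are numbered within a group in column order. Of the columns of per-sample values in this table, 3 match no sample described here, and no script calculates with them, though a first look at the table did. The second table holds the log2 values that the authors deposited as processed data. Its 6 columns share 1 distribution to within 0.0004, each with a median of 7.00, so they had been quantile normalized. Each of its columns had a rank correlation of 1 with 1 array of the same group in the intensity table, which settles its direction. Its common distribution differs by up to 0.397 on the log2 scale from the mean quantiles of the 6 arrays used here, so these 6 arrays alone were not the basis of that normalization. The first look pointed to all columns of the intensity table, so the authors' values may depend in part on the 3 columns left out. The second table served as an alternative only.

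The planned neqc normalization needs control probes or detection p-values, so it could not be run. In its place, limma's normexp model was fitted to all signals of an array (offset 16), followed by quantile normalization over the 6 arrays and log2. This replacement was settled after a first look at its results, and another way to set the background is given among the alternatives. Detection was judged against each array's own background peak, the mode of its log2 signals (kernel bandwidth 0.02), with the SD of the values below the mode. A probe counted as above background at a one-sided normal probability of 0.05, and probes above background on at least 3 of the 6 arrays were kept, 19002 in all. Median signals lay between 131 and 142, and 38.1% to 42.1% of the probes of an array were above background. With 3 arrays per group, the number of arrays limits the precision: the median standard error of a log2 fold change was 0.160.

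Gene symbols came from the platform annotation, in which 28094 probes had 1 gene, 13 had several and 20692 had none. For 39 of the named probes the gene identifier was not in the RefSeq table (GRCh38.p14), and the symbol was kept as given. That table was used only for names and for which genes lie next to each other, since the build of the array's annotation is not given in the sources used here. Each gene was represented by its kept probe with the highest mean, which left 11729 genes from 15748 named probes. Among the 3166 genes with several kept probes, 49 had probes called in opposite directions.

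Log2 values of OM3 and ip1 were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested). An adjusted p under 0.05 was taken as a change. Fold changes are OM3 over ip1, on the scale of normexp with its offset, which shrinks the changes of dim genes. Where a probe was below background on every array of 1 group, the change is given only as a bound, "at least N-fold". Fitted log2 fold changes of such probes appear only where settings or sets of genes are compared or genes are ranked. They rest on background signal. A bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the lowest signal above background and the probe's own signal. Bounds are those of the probe, and another probe of the gene can lie above background. Where a probe was above background on only some arrays of a group, their number is given, and the fold change rests in part on background signal. Of 45 gene lists fixed before the data were examined, the 41 with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Estimated correlations and fry are given beside it.

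Genes were named by a rule also fixed before the data were examined. It takes the ERBB receptors and ligands past the filter, then the 12 largest fitted changes in each direction whose groups did not overlap. Placeholder symbols are left out. The rule adds up to 4 members of each list that was shifted or had at least 5 changed members. Up to 4 changed markers of other cell types are added too. This gave 167 genes, of which the text names a part. A further 34 genes were chosen after their values were seen, and the text marks them.

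The scripts were tested on simulated data made from the ip1 and OM3 arrays, with 11073 genes past the filter. Of the genes changed by known amounts, 13 of 48 were recovered at 1.5-fold, 30 of 48 at 2-fold, 47 of 48 at 4-fold and 46 of 46 at 8-fold. Among 144 calls, 8 were false. Only genes far above background in ip1 were changed, and they were few among all genes. Dim genes and normalization under changes of most genes were therefore not tested. The shifted list was called, and 0 of the other lists among 38 were. The simulated noise was independent between genes, so this does not test list calls where genes vary together.

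The alternatives covered the background correction and its offset, the normalization between arrays, the authors' value table, the filter, the treatment of several probes per gene, the variance model, the test, the list test, and leaving out each array. Slide or chip positions are not given in the sources used here, so no block for them was fitted, and a difference in slide or day between the groups could not be examined.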

Results

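The data are 6 array profiles labelled as SKOV3, an established human ovarian carcinoma line known for its high ERBB2 level. Of these, 3 are of the parental subline ip1 and 3 of OM3, a subline labelled as metastatic. Whether the OM3 RNA comes from a descendant of ip1 could not be settled, as described under the other observations. The one comparison of the design, OM3 against ip1, asks which genes differ between metastatic and parental cells. The study is known for its interest in the receptor ERBB3 and its ligand NRG1 in spread to the omentum, the fatty apron of the abdomen. Arrays of 1 group correlated at 0.984 to 0.988 over the tested genes, and arrays of different groups at 0.797 to 0.813. The first principal component held 91.2% of the variance.

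Both NRG1 and ERBB3 were higher in OM3, while ERBB2, EGFR and most of the measured EGF-type ligands were lower. NRG1, a ligand of ERBB3, rose by 2.37 ± 0.14 on the log2 scale (SE, n = 3 + 3, adjusted p = 1.59e-06), from 9.58 ± 0.15 to 11.94 ± 0.12 (SD). The main probe of ERBB3 was below background on the 3 ip1 arrays and at least 2.39-fold higher in OM3 (adjusted p = 5.41e-05), where its level, 7.21 ± 0.04, was low. ERBB2, the preferred partner receptor of ERBB3, was at 12.79 ± 0.05 in ip1 and 9.26 ± 0.15 in OM3, a log2 fold change of -3.53 ± 0.13 (adjusted p = 1.11e-07).

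EGFR had a log2 fold change of -3.60 ± 0.17 and its ligand HBEGF one of -2.96 ± 0.13. TGFA, another EGFR ligand, was at least 38.9-fold lower in OM3, and BTC at least 1.36-fold lower. NRG2 (-0.50 ± 0.20, above background on 1 of 3 OM3 arrays) did not pass the test (adjusted p = 0.0575), nor did EGF, which was below background on the 3 OM3 arrays (adjusted p = 0.0925). Of the 9 measured genes of the list ERBB receptors and ligands, 2 rose, 5 fell and 2 did not pass. Adjusted over the list alone, 2 rose and 6 fell. The list as a whole was shifted towards lower values (adjusted p = 0.0391), with adjusted p = 0.270 with an estimated correlation. The call of the list was lost with cyclic loess (adjusted p = 0.0799), with a stricter filter (0.0706) and without replicate 1 of ip1 (0.0591). ERBB4, NRG3, NRG4 and EREG did not pass the filter on dim probes, and AREG and EPGN had no named probe.

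The 3 NRG1 probes past the filter gave log2 fold changes from 1.27 (above background on 1 of 3 ip1 arrays) to 2.37, all past the test. The other probes of ERBB2 and EGFR also passed but were dimmer. That of ERBB2 was at 6.21 in ip1 and below background on the 3 OM3 arrays (adjusted p over all probes = 0.00583), and that of EGFR gave -1.15 ± 0.17 (above background on 2 of 3 OM3 arrays). Of the ERBB3 probes, a second one gave 0.51 ± 0.27 (adjusted p over all probes = 0.139) and was above background on 2 of the 3 ip1 arrays. When the filter and the choice of probe were redone without replicate 1, 2 or 3 of OM3, that second probe stood for ERBB3. The ERBB3 log2 fold change was then 0.25, 0.47 and 0.81, with adjusted p = 0.403, 0.241 and 0.00975.

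**Figure D1:**
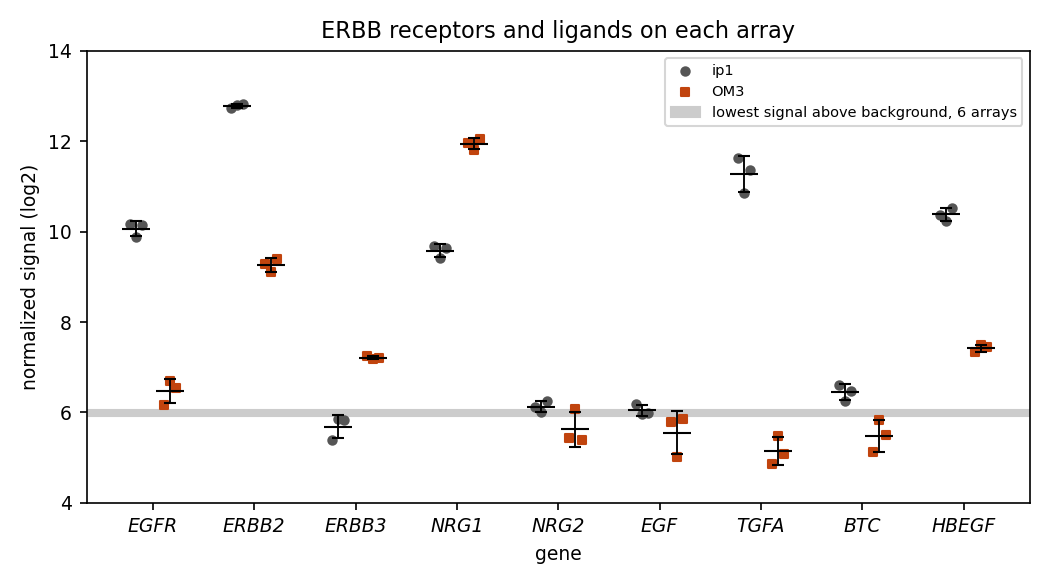
Normalized log2 signal of the ERBB receptors and ligands past the filter (gene on the x axis) on the 3 ip1 arrays (grey circles) and the 3 OM3 arrays (orange squares), with mean and SD as bars; the grey band spans the lowest signal above background on the 6 arrays. ERBB2 lies at 12.79 in ip1 and 9.26 in OM3, NRG1 at 9.58 and 11.94, and ERBB3 at 5.69, under the band, and 7.21.

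Over all genes, 3658 were higher and 3042 lower in OM3, together 57.1% of the 11729 tested. There were 1500 genes higher in OM3 by at least 2-fold and 1620 genes lower in OM3 by at least 2-fold. The authors' value table gave 850 and 999 at that size, values without background correction gave 951 higher, and probes above background on all 6 arrays gave 795 lower. Genes whose 3 OM3 values all lay on one side of the 3 ip1 values made up 64.2%, where chance gives 10%. The median log2 fold change was 0.09, and cyclic loess moved it by -0.107, so small changes depend on the scaling. With cyclic loess the balance turned, to 3077 higher and 3492 lower. Changes of at least 16-fold were found for 67 higher and 213 lower genes.

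The largest increases included UQCRH, a subunit of respiratory complex III (at least 227-fold), the matrix proteases MMP3 (8.25 ± 0.18 on the log2 scale) and MMP10 (7.19 ± 0.14), and the smooth muscle actin gene ACTA2 (8.17 ± 0.12). UQCRHL, a near-identical copy of UQCRH, rose by 8.14 ± 0.19, and the probes cannot separate the 2 with certainty. COL5A2 (7.30 ± 0.23), SPOCK2 (7.18 ± 0.15) and NEFH (6.88 ± 0.16) also rose. TMEM30B was at least 45.8-fold higher, NDN at least 48.4-fold, and the transcription factor gene ISL1 was 84.7-fold higher. The matricellular protein gene POSTN rose as well (adjusted p = 6.69e-08). On the ip1 arrays, MMP3, UQCRHL and SPOCK2 were above background on 2 of 3, and COL5A2, NEFH and POSTN on 1 of 3. The largest decreases included calcium-binding S100 proteins: S100A4 (-9.27 ± 0.28, above background on 1 of 3 OM3 arrays), S100A6 (at least 326-fold lower), S100A10 (at least 345-fold lower) and S100A16 (at least 208-fold lower). CAV1, the main caveolar coat protein (at least 219-fold), the tissue factor gene F3 (at least 208-fold), TGFBI (at least 131-fold), OCIAD2 (at least 135-fold), SPINT2 (at least 145-fold) and PODXL (at least 139-fold) were also lower. The main probe of the hyaluronan receptor CD44 was at least 205-fold lower, while another of its 3 kept probes gave -0.36. Among the genes given here with bounds, the adjusted p ran from 3.69e-09 for S100A6 to 0.00276 for BTC.

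**Figure D2:**
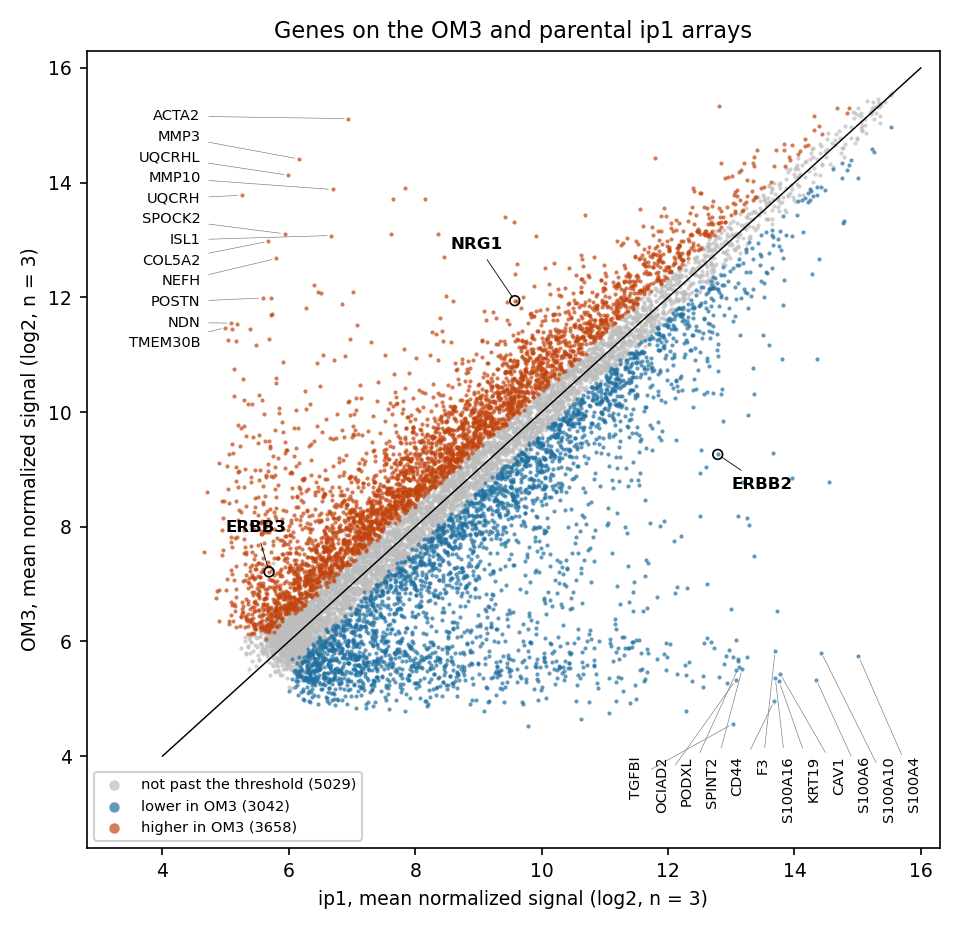
Mean normalized log2 signal of each tested gene in ip1 (x axis, n = 3) and OM3 (y axis, n = 3); orange marks genes higher in OM3 (3658), blue genes lower (3042) and grey those not past adjusted p 0.05. The named genes at the upper left and lower right are the 12 largest fitted changes in each direction, some of which rest on background signal. ERBB3, NRG1 and ERBB2 are circled, and the line marks equal values.

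Epithelial genes were mostly lower in OM3: of 18 measured, 14 fell, 1 rose and 3 did not pass the test (list adjusted p = 3.91e-06, adjusted p = 0.146 with an estimated correlation). Adjusted over the list alone, 15 fell and 1 rose. The keratin KRT19 was at least 217-fold lower, KRT7 had a log2 fold change of -7.56 ± 0.28 (above background on 1 of 3 OM3 arrays), and MAL2 was at least 24.3-fold lower. The member that rose was EPCAM, an epithelial adhesion molecule (0.97 ± 0.13, chosen after its values were seen). CDH1, which encodes E-cadherin, was dim in both groups, at 6.19 and 5.71 (-0.48 ± 0.20, above background on 1 of 3 OM3 arrays, also chosen afterwards), and was not called. Mesenchymal genes went both ways: of 16, 5 rose and 8 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.136). ACTA2 and POSTN rose, whereas S100A4, TGFBI and the receptor kinase AXL (at least 94.1-fold lower) fell. VIM, which encodes vimentin, was high in both groups, at 15.01 and 15.30 (chosen after its values were seen), and its difference of 0.29 ± 0.15 did not pass.

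Matrix genes changed in both directions, with more lower than higher. Of 22 collagens and basement membrane genes, 6 rose and 15 fell (list adjusted p = 0.00373, adjusted p = 0.159 with an estimated correlation). The fibrillar collagen genes COL5A2 (7.30 ± 0.23) and COL3A1 (at least 45.2-fold) rose, and the basement membrane collagen gene COL4A1 had a log2 fold change of -6.83 ± 0.23. In the same arrays 7 of 9 fibroblast markers rose and 1 fell (list adjusted p = 0.00654, adjusted p = 0.159 with an estimated correlation): POSTN, COL3A1 and DCN (at least 6.27-fold) were higher, and MFAP5 was at least 62.5-fold lower. COL3A1 belongs to both lists. Of 11 integrins, 2 rose and 8 fell (list adjusted p = 0.0131, adjusted p = 0.159 with an estimated correlation), with ITGB4 at least 20.8-fold lower, ITGA3 at -4.40 ± 0.13 and ITGA6 at -3.78 ± 0.17. Of 23 matrix proteases and inhibitors, 7 rose and 14 fell (list adjusted p = 0.0344, adjusted p = 0.159 with an estimated correlation). The increases included MMP3, MMP10 and the collagenase gene MMP1 (6.07 ± 0.14, chosen after its values were seen), while the urokinase gene PLAU was at least 119-fold lower and TIMP2 had a log2 fold change of -6.69 ± 0.26. On the OM3 arrays, COL4A1 was above background on 1 of 3, and ITGA6 and TIMP2 on 2 of 3. Counts adjusted over the list alone were the same for these 4 lists. Cyclic loess ended the call of the protease list (adjusted p = 0.0662).

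Inflammatory and antigen presentation genes were more often lower than higher in OM3. Of 14 chemokines and cytokines, 10 fell and 1 rose (list adjusted p = 0.000158, adjusted p = 0.146 with an estimated correlation), and 11 fell when adjusted over the list alone. CXCL8, a neutrophil attractant, had a log2 fold change of -7.52 ± 0.21, IL1A was at least 44.4-fold lower and IL6 at least 20.6-fold lower. Of 14 NF-kappaB targets, 10 fell and 1 rose (list adjusted p = 0.000898, adjusted p = 0.146 with an estimated correlation), among them IER3 (-5.09 ± 0.12) and TNFAIP3 (-3.83 ± 0.21). Of 31 interferon-stimulated genes, 16 fell, 4 rose and 11 did not pass (list adjusted p = 0.0306, adjusted p = 0.159 with an estimated correlation). BST2, which tethers budding virus, was 32.1-fold lower, while GBP1 rose by 3.92 ± 0.23. Of 16 MHC class I and antigen processing genes, 11 fell and 3 rose (list adjusted p = 0.00654, adjusted p = 0.363 with an estimated correlation), or 4 when adjusted over the list alone. HLA-F (-3.97 ± 0.14) and HLA-B (-2.65 ± 0.14) fell and HLA-C rose by 2.13 ± 0.23, though these genes are similar in sequence and their probes are uncertain to that extent. CXCL8 and BST2 were above background on 1 of 3 OM3 arrays and TNFAIP3 on 2 of 3, and GBP1 was above it on 1 of 3 ip1 arrays and HLA-C on 2 of 3. Counts adjusted over the list alone were the same for the NF-kappaB and interferon lists.

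Markers of ovarian cancer and of Mullerian origin were mostly lower in OM3, with 9 of 12 lower and 1 higher, also when adjusted over the list alone (list adjusted p = 0.00218, adjusted p = 0.146 with an estimated correlation). The lineage transcription factor genes PAX8 and SOX17 were at least 42.2-fold and at least 20.4-fold lower, mesothelin (MSLN) at least 29.2-fold lower, and the folate receptor gene FOLR1 had a log2 fold change of -4.81 ± 0.18. Of 10 stem and progenitor markers, all were called, 3 higher and 7 lower, also when adjusted over the list alone; the list was not shifted as a whole (adjusted p = 0.178). LIN28B, which blocks maturation of let-7 microRNAs, was at least 18.3-fold higher and CD24 had a log2 fold change of -7.45 ± 0.20. In the Wnt pathway list, 11 of 21 fell and 1 rose (adjusted p = 0.00467, adjusted p = 0.148 with an estimated correlation), with the ligand genes WNT7A at -5.36 ± 0.20 and WNT7B at -4.37 ± 0.20. In the list YAP targets, 9 of 15 fell and 4 rose (adjusted p = 0.0391, adjusted p = 0.167 with an estimated correlation). CCN2 fell (-5.05 ± 0.14) and ANKRD1 rose by 4.74 ± 0.16. The YAP call was lost with cyclic loess (adjusted p = 0.0713), with the mean of a gene's probes (0.0556) and without replicate 2 of ip1 (0.0518). Of 21 angiogenic factors, 15 fell and 4 rose (adjusted p = 0.00218, adjusted p = 0.146 with an estimated correlation). THBS1, an inhibitor of vessel growth, had a log2 fold change of -6.56 ± 0.22 and EFNA1 one of -4.59 ± 0.14. Of 13 selectin, platelet and vascular adhesion molecules, 9 fell and 2 rose (adjusted p = 0.0137, adjusted p = 0.159 with an estimated correlation). JAM3 rose by 5.81 ± 0.13, and CD9 was at least 10.2-fold lower. On the OM3 arrays, FOLR1, CD24, WNT7A and WNT7B were above background on 1 of 3 and THBS1 on 2 of 3. These 4 lists had the same counts when adjusted over the list alone.

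Cholesterol synthesis genes were shifted upwards: of 19, 9 rose and 1 fell, and 10 rose when adjusted over the list alone (adjusted p = 0.0344, adjusted p = 0.159 with an estimated correlation). EBP rose by 3.25 ± 0.22 and DHCR7 by 1.98 ± 0.14, both enzymes of late sterol synthesis, and the sterol carrier gene STARD4 was at least 5.94-fold higher. Genes of fatty acid synthesis, uptake and oxidation went both ways, with 14 of 30 higher and 8 lower, also when adjusted over the list alone (adjusted p = 0.312). The fatty acid receptor gene CD36 was at least 39.2-fold higher, the lipid droplet gene PLIN2 rose by 4.45 ± 0.18, and PPARG, a regulator of fat cell genes, had a log2 fold change of -3.26 ± 0.15. Of 6 metallothioneins, which bind zinc and copper, 5 fell, also when adjusted over the list alone (adjusted p = 0.00467, adjusted p = 0.198 with an estimated correlation), with MT2A at -5.78 ± 0.20 and MT1G at least 13.9-fold lower. In the ERK list, 9 of 17 rose and 6 fell (7 when adjusted over the list alone), without a shift of the list (adjusted p = 0.676). SPRY1 (5.50 ± 0.13) and DUSP6 (3.24 ± 0.20), both feedback inhibitors of this pathway, rose, and DUSP4 was at least 5.14-fold lower.

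Genes of DNA replication and of mitosis went both ways. Of 32 DNA replication genes, 8 rose and 4 fell (6 and 3 when adjusted over the list alone), and of 30 genes of G2 and mitosis, 6 rose and 12 fell, also when adjusted over the list alone. Neither list was called (adjusted p = 0.499 and 0.34). These counts depend on the scaling: 13 and 2 for DNA replication with median centring but 6 and 5 with cyclic loess, and 8 and 9 for G2 and mitosis with median centring but 6 and 13 with cyclic loess. RRM2 rose by 1.23 ± 0.14, and CENPA had a log2 fold change of -1.11 ± 0.12. Of 41 cytosolic ribosomal protein genes, 34 did not pass, 1 rose and 6 fell (3 when adjusted over the list alone), and 3 rose and 10 fell in the authors' value table. Of 11 CDK inhibitors and other brakes of the cell cycle, 3 rose and 5 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.34, median log2 fold change -0.55). CDKN2A, which encodes p16, was below background on the 3 ip1 arrays and at least 11.2-fold higher in OM3. CDKN1B rose by 1.86 ± 0.14 and GADD45A had a log2 fold change of -2.30 ± 0.13.

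Further lists went both ways and were not shifted by camera. Of 31 glycolysis and hypoxia genes, 11 rose and 12 fell (adjusted p = 0.676), among them the glucose transporter genes SLC2A3 (2.99 ± 0.16) and SLC2A1 (-2.71 ± 0.15). The list's median log2 fold change was -0.20 and its mean 0.02. Of 30 oxidative phosphorylation genes, 9 rose and 7 fell (6 when adjusted over the list alone), and with cyclic loess 6 rose and 9 fell. Of 15 heat shock genes, 9 rose and 3 fell, with a median of 0.40 and a mean of -0.22. The chaperone genes HSPA1A (-6.59 ± 0.28) and HSPB1 (-4.37 ± 0.14) had the lowest values of the list. Of 20 NRF2 targets and aldo-keto reductases, 7 rose and 8 fell, with a median of 0.06 and a mean of -0.17: the glutathione transferase gene GSTA4 rose by 4.23 ± 0.34 and AKR1C3 had a log2 fold change of -5.54 ± 0.18. Of 15 Notch pathway genes, 5 rose, among them the target gene HEY1 (3.11 ± 0.15), and 8 fell. Of 14 FOXO targets and PI3K-AKT feedback genes, 5 rose and 5 fell (6 when adjusted over the list alone), including CITED2 (3.97 ± 0.13) and the insulin receptor substrate gene IRS2 (-3.71 ± 0.26). Of 23 apoptosis regulators, 2 rose and 9 fell (adjusted p = 0.105), with the pro-apoptotic gene BIK at least 10.1-fold lower and the anti-apoptotic gene BCL2L1 at -2.87 ± 0.15. Of 8 drug transporters, 2 rose and 3 fell, with the efflux pump gene ABCB1 at least 5.44-fold higher and ABCC3 at -4.19 ± 0.20. Of 13 reference genes, 3 rose and 4 fell, PPIA (-1.17 ± 0.20) and B2M (-1.14 ± 0.12) among the latter, with a median of 0.02 and a mean of -0.11. Of 14 unfolded protein response genes 5 rose and 3 fell, of 18 genes of the amino acid response 5 rose and 7 fell, and of 14 TGF-beta targets 4 rose and 7 fell. On the OM3 arrays, HSPA1A was above background on 2 of 3, and AKR1C3, IRS2 and ABCC3 on 1 of 3, and GSTA4 was above it on 2 of 3 ip1 arrays. Where no second count is given, counts adjusted over the list alone were the same.

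Markers of other cell types did not move together. Mesothelial markers were lower (5 of 7, list adjusted p = 0.00801, adjusted p = 0.159 with an estimated correlation), as were adipocyte markers (3 of 5, list adjusted p = 0.0293, adjusted p = 0.159 with an estimated correlation). Without a filter the adipocyte call was lost (adjusted p = 0.395). Of the 5 leukocyte markers 2 were lower, CD68 4.01-fold lower and LAPTM5 at least 1.51-fold lower, and the list of 5 endothelial markers was not called (adjusted p = 0.767). Counts adjusted over the list alone were the same for these 4 lists. HBA2, a haemoglobin gene from a list of 2 measured erythroid markers, rose by 2.49 ± 0.20 and was above background on 1 of 3 ip1 arrays.

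Of the 41 lists tested, 19 were shifted with the preset correlation, 2 upwards and 17 downwards, and 0 with an estimated correlation (11 at an unadjusted p under 0.05). By fry, 34 lists moved on balance in one direction and 40 changed in either. Fry asks whether a list's genes change at all, not whether they change more than other genes. With 57.1% of all genes called, a list can pass it without a shift of its own. With probes above background on all 6 arrays, a filter that leaves out genes found in 1 group alone, 3 of 32 lists were shifted.

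**Figure D3:**
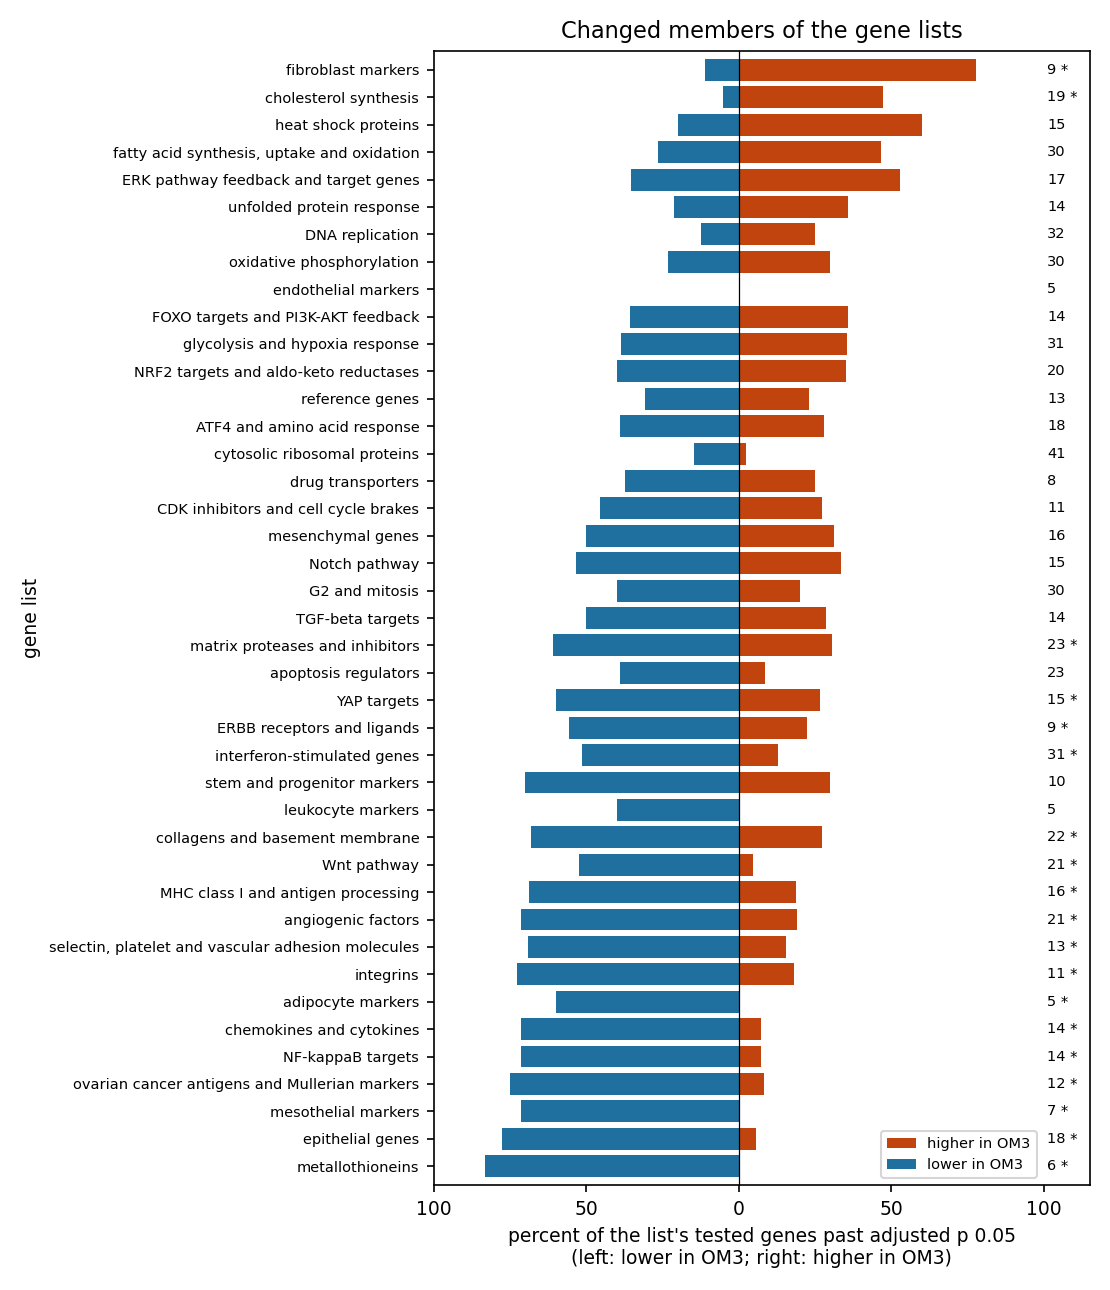
Percent of the tested genes of each list (y axis) that passed adjusted p 0.05, to the left for genes lower in OM3 (blue) and to the right for genes higher (orange); the number of tested genes stands at the right, with an asterisk where the list was shifted by camera with the preset correlation. Fibroblast markers (7 of 9 higher) and epithelial genes (14 of 18 lower) lie near opposite ends.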

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

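The background taken from the mode and the leave-one-out runs with a redone filter were chosen after seeing the data. The number of genes higher in OM3 by at least 2-fold was 951 without background correction and 850 in the authors' value table, and that of genes lower in OM3 by at least 2-fold was 999 in that table and 795 among genes above background on all 6 arrays, where fewer genes (8930) were tested. Against a log2 bound of 0.5, treat left 1675 higher and 1701 lower. Lists shifted fell to 3 with the filter on all 6 arrays and 0 with an estimated correlation. By fry, which asks another question, 34 passed. Leaving out each array with the same probes kept gave 18 to 19 lists and 1.36 to 1.60 for the fitted ERBB3 log2 fold change. The first version of this check redid the filter and the probes on 5 arrays. It gave 6 to 20 lists (6, 10 and 7 without replicate 1, 2 and 3 of ip1) and 0.25 to 1.60 for ERBB3. The version with kept probes was put first after both had been seen, because a redone filter drops genes found in 1 group alone. FGF18 and DKK3, named by the rule but not described above, changed where another probe was chosen. In the main run FGF18 was at least 6.04-fold lower. Its log2 fold change was 0.092 with the filter on all 6 arrays, and ranged from -3.63 to 0.16 with the redone filter. The DKK3 log2 fold change ranged from -7.63 with kept probes to 0.46 with a redone filter. CDK12 and IKZF3, which were not called, changed sign around 0: the CDK12 log2 fold change was -0.12 with cyclic loess, -0.062 with array weights and -0.099 to 0.27 without single arrays, and IKZF3 -0.26 to 0.11. Of 4740 alternative values of single named genes other than ERBB3, 4695 kept direction and side of the threshold, 16 lost and 10 gained a call, and 19 changed sign. A gene that a setting no longer tested gave no value there, and treat was left out. Many of the named genes were picked for large changes. Of all 6700 calls, the ordinary two-sample test kept 5626 and treat 3376. Of 477 alternative values of the shifted lists, 410 kept their call and 67 lost it. A slide block was not run. No paired analysis was possible because the groups share no replicate numbers. Signal over background limits dim genes: 623 genes were found on every ip1 and no OM3 array, and 251 the reverse.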

Other observations

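All tests in this part were chosen after the values were seen, and so were the gene families and the genes named only here. The tests on the ERBB2 block and on neighbouring genes were devised after a scan of neighbouring runs had been seen.

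For gene families only counts are given. No family here was tested as a set or against another, and 57.1% of all genes were called. Among developmental families, the HOXC genes help to set position along the body axis. Of 8 measured HOXC genes, 8 were higher in OM3 (7 with cyclic loess). The main probes with the largest changes were those of HOXC6 (log2 fold change 5.56 ± 0.13), HOXC8 (3.31 ± 0.15) and HOXC13 (3.17 ± 0.20). HOXC13 was above background on 1 of 3 ip1 arrays, and another of the 3 kept HOXC6 probes gave 0.76. Of 8 HOXD genes, 4 were lower, 4 not called and 0 higher under each scaling run, with HOXD1 at least 7.50-fold lower and HOXD8 at -2.21 ± 0.39 (above background on 1 of 3 OM3 arrays). Of 10 HOXB genes, 3 were higher and 2 lower (3 lower with cyclic loess and in the authors' value table), and of 10 SOX genes, 3 were higher (2 under some scalings) and 6 lower. The cardiac factor gene NKX2-5 was at least 24.7-fold higher and TBX2 rose by 4.18 ± 0.15. The 4 measured LIN28 and IGF2BP genes were all higher (3 with cyclic loess), among them IGF2BP3 (2.36 ± 0.16) and LIN28B (at least 18.3-fold).

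Further families are known from epithelial and membrane biology. Of 11 measured S100 genes, 10 were lower in OM3 under each scaling run, among them S100A11 (at least 77.3-fold) and S100A3 (-5.48 ± 0.21). Of 16 keratin genes, 10 were lower and 1 higher (9 to 11 lower across scalings), with KRT80 at -7.42 ± 0.38. Of 9 annexins, 7 were lower and 1 higher under each scaling run, with ANXA3 at -5.45 ± 0.15 and ANXA1 at -3.05 ± 0.14. S100A3 and KRT80 were above background on 1 of 3 OM3 arrays and ANXA3 on 2 of 3. Other families went both ways: 2 of 6 caveolins and cavins were higher and 4 lower, 2 of 11 claudins were higher (1 with cyclic loess) and 6 lower, and of 3 gap junction genes 1 was higher and 1 lower.

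By their main probes, genes switched between background and bright signal in both directions: 75 genes above 10 on the log2 scale in ip1 were at background on every OM3 array, and 16 the reverse. Only 26 of the 75 and 7 of the 16 had another kept probe, so the rest could not be checked this way. For 11 of the 26 and 1 of the 7, another kept probe was above background on at least 1 array of the dim group. With no scaling between arrays, 86 genes (69 and 17) switched, so the switches are present in unscaled signals. The background calls came from unscaled signals in each setting, and only the cut of 10 could move. The count therefore could hardly fall and is no test of scaling. Whether a share of 1% or more of parental RNA remained in OM3, beside that of other cells, was not settled. Of 2866 genes with ip1 signals over 1000, 55 kept under 1% of it in OM3 with 2 background SDs added. Noise that is independent between arrays gives at most 0.762 such genes. Background that a probe repeats on each array could give more and was not modelled, and a smaller share is not addressed. CDKN2A, which the SKOV3 line is reported to have lost and a descendant lacking it could not express, was above background in OM3 alone, so RNA of a line that does not descend from ip1 may be on the OM3 arrays. This cannot be told apart from reprogramming of a descendant, since signal at background does not show whether the ip1 cells used here lack CDKN2A or keep it silent, and no genotypes were used here.

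ERBB2 lay among genes that were mostly lower in OM3. Of its 9 tested neighbours within 250 kb, 7 were lower (PPP1R1B, STARD3, PGAP3, MIEN1, GRB7, GSDMB and ORMDL3; another GSDMB probe gave 0.48), and CDK12 and IKZF3 were not called, while of the 6 tested genes next outside, FBXL20 (log2 fold change -0.99) and PSMD3 (-0.38) were lower and 4 were not called. The median log2 fold change of the neighbours was -1.23, so ERBB2 was not the only gene of the block that was lower. Only 0.607% of windows of equally many consecutive genes, those overlapping the block included, had a median as low. The median and this share describe the block rather than testing a cause, since a scan of neighbouring runs had been seen first. A lower copy number of this block may be a candidate explanation, though the changes within it were uneven. Fitted log2 fold changes ran from -7.31 for PPP1R1B to 0.05 for CDK12. That of MIEN1, next to ERBB2, was -1.23, against -3.53 for ERBB2 itself. Shared regulation of the block was not tested, and a line without the ERBB2 amplification of SKOV3 would give the same values.

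Neighbouring genes changed alike across the genome. Log2 fold changes of consecutive genes correlated at 0.197, and at 0.166 without pairs sharing 3 letters of their symbols, above the highest of 1000 shuffles (0.0292), which argues against neighbouring paralogs as the whole cause. Genes 6 to 20 positions apart correlated at 0.0352, above the highest shuffle of 0.00873, so copy number differences between the OM3 and ip1 cells may contribute, though the correlation is small. Genes are not independent replicates, and shared chromatin domains stay open. The median log2 fold change of chromosome 4 was 0.45, above the highest chromosome median of the shuffles (0.34).

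With 3 arrays per group there are 10 splits of the 6 arrays, too few for a share under 0.05, and only the real split, 1 of the 10, gave counts as large as the real ones. The real split gave 3658 higher and 3042 lower genes, 1500 and 1620 by at least 2-fold, and 19 lists. The highest of the other splits gave 0 genes and 7 lists. Each of these splits mixes ip1 and OM3 arrays on both sides, so the group difference adds to the spread. Their 0 genes thus say little about chance.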
